A study of Homo sapiens with 62 samples.

How the data were processed

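PolyA RNA-seq was measured in 62 libraries, 31 groups of 2, from hESC of the line WIBR3 and from organoids grown from it. Per the submitters' processing notes, reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.7 and cutadapt 4.1, aligned to GRCh38 with STAR 2.7.10a and counted with featureCounts 2.0.1, and the authors ran DESeq2 1.36.0 in R 4.2.0. The expression table deposited by the authors holds TPM for 37415 genes in each library, and each library adds up to 1000000 TPM. For each of 2 knockout clones in 5 cell types, the authors deposited a DESeq2 table, 10 in all, which gives the log2 fold change against CTR, the base mean (a count-based signal), the p-value and the adjusted p-value. Counts per library were not used here, so the depth of a library is unknown and no counting interval can be given. Whether the libraries were stranded is not stated, so values of antisense and overlapping genes are uncertain, as are those of 707 genes whose symbol occurs more than once.

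Each column of the TPM table was assigned to its group from the labels. No pair of libraries was identical, and between 16989 and 20396 genes reached 1 TPM in a library. The correlation of log2(TPM + 1) between the 2 libraries of a group ranged from 0.932 to 0.987. Gene positions and types came from GENCODE release 29, which gave a position for 33351 identifiers; 12908 genes had an identifier and no symbol, and these were tested and not named.

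Own fits were made with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with empirical Bayes moderation that follows the mean level. A gene was tested when it reached 1 TPM in at least 2 libraries of the fit, and for the average over cell types and its interaction when it did so in each of the 5 cell types. The tests were two-sided, p-values were adjusted by Benjamini and Hochberg over all genes tested, and a gene was called at an adjusted p under 0.05. The PF-127 comparisons came from 1 fit of 16 libraries, with each time point, their average and the interaction with time as contrasts. The knockout comparisons averaged both clones against CTR within a cell type, and over the 30 libraries for the average, the interaction and the contrast of the clones. Each clone was its own group in these fits, so differences between the 2 clones did not enter the spread behind the p-values. CTR organoids were compared with CTR hESC, and WT organoids with each other by day and by the conditions named PN96, Chip and SPIN. The WT nephron libraries of day 7 have no partner group and entered no comparison. The DESeq2 tables were read as deposited by the authors, with the direction taken from the sign of NEAT1.

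Genes were named by a rule. NEAT1 came first in each knockout comparison. Among called genes with a symbol that reached a mean of 5 TPM in the higher group and whose groups did not overlap, and that changed in the same direction in both clones for the knockouts, the 6 largest rises and the 6 largest falls were eligible. From each list up to 4 called members with the largest change were eligible, or the first 2 as listed where none was called. A few short RNA genes that the rule selected were left out of the text, because polyA libraries measure them poorly. There were 35 lists with 432 genes, and a list was tested when at least 3 of its genes were measured. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry.

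Alternatives fixed before the data were opened were a pseudocount of 0.1, no filter, a filter of 5 TPM, rescaling by size factors, a block for the replicate number, leaving out each library, each clone alone, a pooled fit of the knockout or CTR libraries, and a fit of each PF-127 time alone. Chosen after seeing the data were the removal of a smooth trend on GC percent or on transcript length from each cortical WT library, a fit without the SPIN libraries, and TPM without mitochondrial mRNAs. The criterion for GC asked whether more than a given share of the genes stayed called. It was first read from the total number called after the removal, 6056, and then from the genes lower in SPIN that stayed called, which changed its outcome. Libraries were also relabelled at random within time points or cell types, 100 times for each comparison of at least 3 libraries per group.

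The procedure was tested on simulated data with the spread of these libraries and 200 planted changes, 100 of 2-fold and 100 of 4-fold. The share recovered at 2-fold was 93.0% for PF-127 at 24 h, 98.0% for its average, 65.0% for the knockout in nephron and 28.0% in lung organoids, and 99.0% for the average over cell types. It was 24.0% for cortical organoids against hESC, 19.0% for cortical and 40.0% for hepatic Chip against PN96. At 4-fold the lowest share was 65.0%. None of the planted changes was called with the wrong sign, and between 0 and 18 unchanged genes were called. Single values of some genes are not reported here.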

Results

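RNA levels were compared in 62 polyA RNA-seq libraries from human embryonic stem cells (hESC) of the line WIBR3 and from cortical, hepatic, lung and nephron organoids grown from it. The libraries form 31 groups of 2. In PF-127 (Pluronic F-127, a block copolymer that gels on warming) or without it, hESC were sampled at 0, 1, 4 and 24 h. In the same line, 2 clones with the long non-coding RNA gene NEAT1 knocked out and a control (labelled CTR) were sampled as hESC and as 4 kinds of organoid. Levels are the authors' deposited TPM (transcript abundance scaled to the same total in each library), given as mean ± SD over the 2 libraries of a group, or the 4 libraries of both clones. Fold changes and log2 changes ± standard error came from limma on log2(TPM + 1), with genes that reached 1 TPM in at least 2 libraries tested, and p-values adjusted over all genes tested. On that scale the change of a gene with few TPM is understated. A gene rose or fell, against the other group, where the adjusted p was under 0.05. The genes named for the size of their change also had all libraries of one group above all libraries of the other. Lists of marker and pathway genes were fixed before the data were examined, and list calls came from camera with a preset correlation of 0.01; of 170 list calls over 23 comparisons, 4 held with an estimated correlation. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries. TPM keeps no depth, so the depth of each library is unknown here.

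The first question was what PF-127 does to hESC. At 4 h the heme-degrading enzyme HMOX1 was at 79.1 ± 2.95 TPM with PF-127 and 145 ± 2.93 TPM without it, 1.83-fold lower (log2 change -0.87 ± 0.06, adjusted p = 0.00021). ACSS2 fell 1.91-fold from 59.1 ± 4.65 to 30.5 ± 1.44 TPM (adjusted p = 0.0028). The mevalonate kinase MVK was 1.55-fold lower, at 18.5 ± 0.971 against 29.3 ± 0.222 TPM (adjusted p = 0.02). At 1 h, with or without PF-127, HMOX1 was at 27.0 to 28.7 and MVK at 16.4 to 17.4 TPM. By 4 h both had risen less with PF-127. At 4 h RAB33A fell 2.13-fold from 20.0 ± 4.02 to 8.81 ± 1.25 TPM (adjusted p = 0.022), and the kinase NUAK2 fell 1.68-fold to 5.57 ± 0.314 TPM (adjusted p = 0.0057). RABGGTB rose 1.45-fold to 48.4 ± 4.44 TPM, ZFC3H1 1.42-fold to 18.3 ± 1.71 TPM and SNHG4 1.34-fold to 81.8 ± 0.743 TPM. TAF7 rose 1.33-fold, SLC38A2 1.32-fold. TARDBP, the only paraspeckle gene of 11 to change, rose 1.28-fold to 132 ± 4.59 TPM.

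Of 16 cholesterol genes 6 fell at 4 h, and 15 fell when adjusted over the list alone. Among them MVD, which makes isopentenyl diphosphate, fell 1.54-fold from 123 ± 4.59 to 79.5 ± 9.21 TPM (adjusted p = 0.047), the sterol carrier STARD4 1.51-fold from 112 ± 1.71 to 73.8 ± 2.81 TPM (adjusted p = 0.02) and the sterol sensor INSIG1 1.48-fold from 213 ± 9.11 to 143 ± 0.0933 TPM (adjusted p = 0.0039). As a set the cholesterol genes fell by camera (adjusted p = 2.2e-19, and adjusted p = 0.0055 with an estimated correlation). At 4 h limma called 41 of 19294 genes, 14 up and 27 down, and 5 of the falls reached 2-fold. The 4 libraries of 4 h fitted alone gave 0 genes, with 2025 at unadjusted p under 0.05. At 0 h it called 0 genes, with 1029 at unadjusted p under 0.05, and at 1 h 0 genes, with 1370 at unadjusted p under 0.05. At 1 h the immediate early gene FOS, first of its list, was at 35.1 ± 2.87 TPM with and 28.9 ± 3.77 TPM without PF-127 (adjusted p = 0.63), and CCN1, first of the YAP targets, at 218 ± 1.53 and 234 ± 3.03 TPM (adjusted p = 0.88). The PF-127 tests shared one fit of 16 libraries, so libraries of other times lent their spread to the test at 4 h. Without one of the 2 PF-127 libraries of 4 h the count became 192 or 3, and without one of the untreated libraries of 4 h 4 or 2. Leaving out either library gave 24 for 0 h with PF-127, 21 for 1 h without it, 23 for 1 h with it, 26 for 24 h without it and 25 for 24 h with it. At 1 h the count became 1 without the second untreated library of that time.

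At 24 h the largest rise that passed was that of CER1. It encodes a secreted antagonist of Nodal, BMP and Wnt on chromosome 9 (GRCh38 14719724 to 14722717) and was at 48.5 ± 5.62 TPM with and 9.97 ± 3.43 TPM without PF-127, 4.61-fold higher (log2 change 2.20 ± 0.18, adjusted p = 0.0003). The Nodal inhibitors LEFTY2 and LEFTY1 rose 2.33-fold to 99.7 ± 6.66 TPM (adjusted p = 0.00049) and 2.24-fold to 170.3 ± 10.5 TPM (adjusted p = 0.0041), and the ligand NODAL rose 2.07-fold from 52.1 ± 2.65 to 109 ± 5.88 TPM (adjusted p = 0.00065). The stress-induced kinase PLK2 rose 2.14-fold to 7.08 ± 0.996 TPM and the forkhead factor FOXB1 2.08-fold to 10.9 ± 1.85 TPM. Of 4 primitive streak genes measured 2 rose, CER1 and the mesendoderm factor MIXL1 (1.94-fold to 4.35 ± 0.103 TPM, adjusted p = 0.019), and the set rose by camera (adjusted p = 1.6e-06, and adjusted p = 0.021 with an estimated correlation). Of 11 ER stress genes 2 rose, ASNS, which makes asparagine (1.64-fold to 102 ± 5.81 TPM, adjusted p = 0.00028), and CHAC1, which degrades glutathione (1.33-fold, adjusted p = 0.046). The integrin subunit ITGB5 rose 1.44-fold from 90.2 ± 0.0579 to 131 ± 2.60 TPM (adjusted p = 0.00031), the transcription factor ETS1 1.67-fold to 48.3 ± 0.601 TPM and the chaperone HSPA8 1.24-fold to 1882 ± 40.9 TPM.

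Among the falls at 24 h, the fatty acid binding protein FABP7 of radial glia, 1 of 3 neural progenitor genes measured and the only one called, fell 2.78-fold from 21.6 ± 4.68 to 7.04 ± 0.496 TPM (adjusted p = 0.00086), the neural factor OLIG3 2.67-fold to 2.04 ± 0.474 TPM (adjusted p = 0.00038) and the histone gene H2BC5 2.72-fold to 3.53 ± 1.17 TPM (adjusted p = 0.014). The antisense RNA FGF12-AS3 was 4.60-fold lower, at 0.665 ± 0.941 against 6.03 ± 0.492 TPM (adjusted p = 0.022); since strandedness is not stated, its assignment is uncertain. The secreted kinase PKDCC fell 2.17-fold to 33.6 ± 6.50 TPM, and PNMT, which makes adrenaline, 2.14-fold to 2.36 ± 1.22 TPM. Of 6 stromal genes 2 fell, the collagens COL1A1 (1.73-fold to 32.9 ± 0.583 TPM, adjusted p = 0.0018) and COL1A2 (1.34-fold to 15.1 ± 0.0802 TPM, adjusted p = 0.018). Of 8 neuron genes 1 fell, the axon protein GAP43, 1.34-fold; further falls were those of the homeobox factors OTX2 and IRX1 1.30-fold and 1.97-fold, SALL1 1.29-fold, the imprinted gene PEG10 1.32-fold and E-cadherin (CDH1) 1.19-fold. Of 16 cholesterol genes 3 fell, LSS to 17.8 ± 0.970 TPM, HMGCS1 1.34-fold and FDPS 1.33-fold, and 7 fell when adjusted over the list alone. Of 12 pluripotency genes 1 fell, LIN28A, 1.13-fold to 1117 ± 2.24 TPM (adjusted p = 0.047). At 24 h limma called 238 genes, 88 up and 150 down, with 9 rises and 20 falls of at least 2-fold. The 4 libraries of 24 h fitted alone gave 0 genes, with 2126 at unadjusted p under 0.05. Without one of the untreated libraries of 24 h the count became 44 or 98, and without one of the PF-127 libraries of 24 h 121 or 94.

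**Figure D1:**
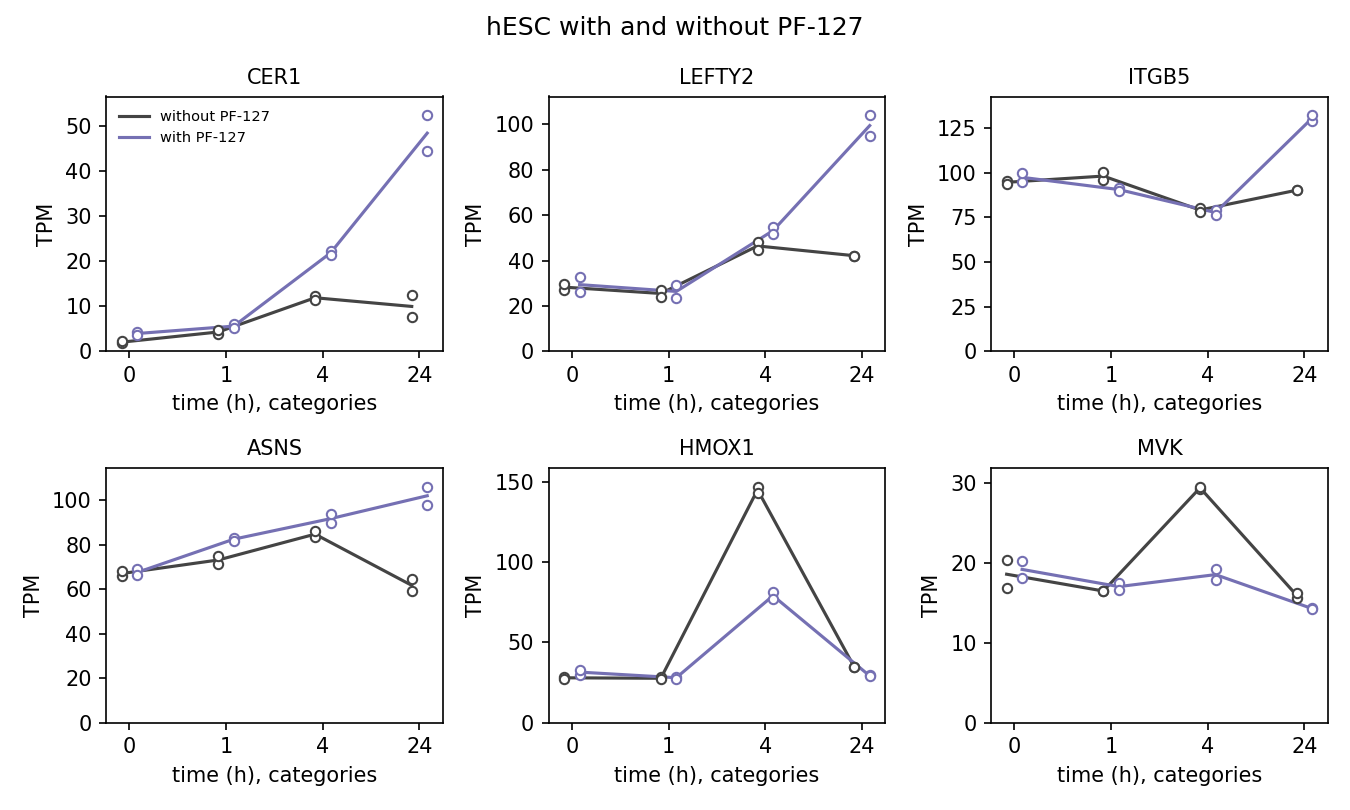
TPM of CER1, LEFTY2, ITGB5, ASNS, HMOX1 and MVK in hESC at 0, 1, 4 and 24 h, with and without PF-127; each point is 1 library and lines join the means of 2 libraries. At 24 h CER1 was at 44.5 and 52.4 TPM with PF-127 and at 7.54 and 12.4 TPM without it.

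Averaged over the 4 times, CER1 was 2.02-fold higher with PF-127 (log2 change 1.02 ± 0.09, adjusted p = 0.0042), with log2 changes of 0.71, 0.32, 0.83 and 2.20 at 0, 1, 4 and 24 h (interaction adjusted p = 0.044). At 0 h, where it was not called, it was at 3.95 ± 0.350 TPM with and 2.04 ± 0.358 TPM without PF-127. ETS1 rose 1.22-fold, ASNS 1.19-fold and the secreted glycoprotein STC2 1.18-fold (adjusted p = 0.0087 for each). IRX1 fell 1.51-fold (adjusted p = 0.025), the polarity protein CRB2 1.26-fold (adjusted p = 0.043), NUAK2 1.25-fold (adjusted p = 0.013), COL1A1 1.24-fold (adjusted p = 0.027), PEG10 1.12-fold (adjusted p = 0.026) and the adhesion protein NLGN4X 1.10-fold (adjusted p = 0.038). None of 16 cholesterol genes fell over all genes, and 13 fell when adjusted over the list alone; as a set they fell by camera (adjusted p = 1.5e-18, and adjusted p = 0.0064 with an estimated correlation). The 10 YAP targets fell as a set (adjusted p = 0.0003, and adjusted p = 0.038 with an estimated correlation), with NUAK2 the only 1 called. Limma called 40 genes, and the share that rose was 32.5%, or 17.5% after rescaling by size factors. The interaction test asked which genes responded differently at different times and called 36. Its first genes were HMOX1, with log2 changes of 0.17, 0.01, -0.87 and -0.25 at 0, 1, 4 and 24 h, ACSS2 with 0.23, 0.07, -0.93 and -0.77, SFRP1, a Wnt antagonist, with -0.02, 0.05, 0.04 and -0.57, and the protease inhibitor SERPINB9 with -0.01, -0.02, -0.03 and 0.55 (adjusted p = 0.0063 for each). ITGB5 followed with 0.04, -0.11, -0.03 and 0.53 (adjusted p = 0.0093), and ASNS with 0.01, 0.17, 0.11 and 0.72 (adjusted p = 0.019).

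These counts rested on single libraries. For the averaged effect the count of 40 became 18 or 19 without one of the untreated libraries of 0 h, 8 or 13 without one of 1 h, 10 or 12 without one of 4 h and 11 or 5 without one of 24 h. Without one of the PF-127 libraries it became 16 or 12 for 0 h, 16 or 7 for 1 h and 64 or 20 for 4 h, and 22 without the first of 24 h. For the interaction the count of 36 became 6 or 13 without one of the untreated libraries of 1 h, 6 without either of 4 h and 1 or 6 without one of 24 h. Without one of the PF-127 libraries it became 18 or 15 for 1 h and 9 or 16 for 24 h, and 65 without the first of 4 h.

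The next question was how loss of NEAT1, the long non-coding RNA that builds nuclear paraspeckles, alters each tissue. NEAT1 lies on chromosome 11 (GRCh38 65422774 to 65445540, annotated as a lincRNA). In hESC it was at 1.87 ± 0.125 TPM in CTR, 0.0105 TPM in clone 1 and 0.0777 TPM in clone 2 (log2 change -1.46 ± 0.23, adjusted p = 0.058). In cortical organoids it was 6.58-fold lower in the clones, from 6.95 ± 2.09 to 0.190 ± 0.0876 TPM (log2 change -2.72 ± 0.28, adjusted p = 0.019). In nephron organoids NEAT1 was 29.9-fold lower, from 37.5 ± 9.59 to 0.295 ± 0.314 TPM (adjusted p = 0.0025), and in hepatic organoids 31.3-fold lower, from 42.0 ± 3.17 to 0.381 ± 0.182 TPM (adjusted p = 0.0049). In lung organoids it was at 16.3 ± 7.75 TPM in CTR, 0.237 TPM in clone 1 and 0.671 TPM in clone 2 (log2 change -3.51 ± 0.33, adjusted p = 0.25). The NEAT1 left in a clone was between 0.0644% and 4.17% of the CTR level of its cell type. Averaged over the 5 cell types NEAT1 fell by 3.51 ± 0.10 on the log2 scale (adjusted p = 1e-14).

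**Figure D2:**
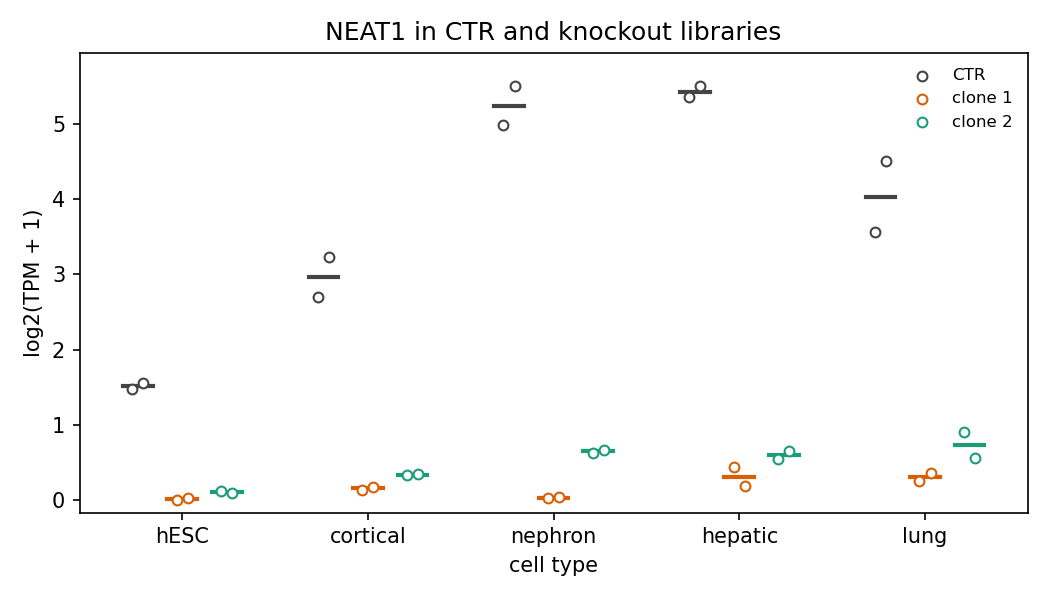
NEAT1 in CTR, clone 1 and clone 2 of hESC and of cortical, nephron, hepatic and lung organoids on a log2(TPM + 1) scale; points are single libraries and bars are means of 2 libraries. CTR means ran from 1.87 TPM in hESC to 42.0 TPM in hepatic organoids, and no clone mean exceeded 0.671 TPM.

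In hESC, NEAT1 fell without passing the test, and long non-coding RNAs were among the largest falls that passed it. P3H2-AS1, an antisense RNA on chromosome 3 (GRCh38 190120964 to 190144846), was 37.9-fold lower in the clones, at 3.75 ± 1.70 against 172 ± 1.29 TPM (log2 change -5.24 ± 0.23, adjusted p = 0.00033); in the 16 libraries of the PF-127 series it ranged from 1.60 to 4.26 TPM. LINC01487 fell 8.26-fold to 1.89 ± 0.375 TPM (adjusted p = 0.0006) and LINC01108 8.22-fold from 59.6 ± 0.983 to 6.79 ± 2.78 TPM (adjusted p = 0.0025), with 32.5 to 75.5 TPM in the PF-127 series. LINC00836 was at 16.3 ± 2.04 TPM in CTR and listed at 0 in the 4 clone libraries (adjusted p = 0.00028). The secreted ribonuclease RNASE1 fell 8.23-fold to 1.31 ± 0.610 TPM and the calcium-binding protein S100A6 7.94-fold to 0.416 ± 0.145 TPM. CER1 fell 3.37-fold to 0.237 ± 0.231 TPM (adjusted p = 0.031), the angiopoietin receptor TEK 3.69-fold to 1.60 ± 0.260 TPM, the matrix protein TNC 2.76-fold to 1.58 ± 0.146 TPM and osteopontin (SPP1) 2.35-fold to 6.71 ± 0.595 TPM. The zinc-finger gene ZNF649 rose 2.05-fold to 42.9 ± 16.6 TPM (adjusted p = 0.0031) and its overlapping antisense RNA ZNF649-AS1 2.46-fold to 62.7 ± 14.7 TPM (adjusted p = 0.01); with strandedness not stated, the reads of these genes cannot be told apart.

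ZNF44 and ZNF138 rose 1.90-fold each in hESC (adjusted p = 0.038 and 0.004), ZNF700 1.86-fold to 24.4 ± 0.809 TPM (adjusted p = 0.004) and ZNF558 1.83-fold to 17.5 ± 1.34 TPM (adjusted p = 0.019). The homeobox factor OTX2 rose 1.43-fold to 45.1 ± 1.94 TPM (adjusted p = 0.031). None of 12 mitochondrial mRNAs changed over all genes, and 10 fell when adjusted over the list alone, MT-ND1, first of its list, being at 8889.6 ± 464 against 10772 ± 300.2 TPM; mitochondrial mRNAs held 19.0% of TPM in CTR, 16.2% in clone 1 and 16.5% in clone 2. Limma called 116 of 19325 genes, 39 up and 77 down, with 5 rises and 61 falls of at least 2-fold; the share that rose was 33.6%, or 19.1% after rescaling. The count became 10 or 21 without one of the CTR libraries, 65 or 57 without one of clone 1 and 68 or 63 without one of clone 2.

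In cortical organoids NEAT1 fell 6.58-fold, and the chemokine gene CXCL11 showed the largest rise. CXCL11, on chromosome 4 (GRCh38 76033682 to 76041415), was at 60.0 ± 14.0 TPM in the clones and 0.216 ± 0.306 TPM in CTR, 49.9-fold higher (log2 change 5.64 ± 0.21, adjusted p = 5.4e-05). ART3, an ADP-ribosyltransferase gene that overlaps it (GRCh38 76011184 to 76112802), rose 5.62-fold to 5.10 ± 0.803 TPM (adjusted p = 0.011). ENPP2, which makes lysophosphatidic acid, rose from 4.62 ± 0.440 to 14.5 ± 3.52 TPM (adjusted p = 0.022) and SHISA2, an inhibitor of Wnt and FGF receptors, 2.41-fold to 45.2 ± 7.19 TPM (adjusted p = 0.011). The proteasome chaperone PSMG3 rose 2.14-fold from 19.7 ± 1.94 to 43.4 ± 4.36 TPM (adjusted p = 0.024) and the nascent-chain protein BTF3 2.07-fold from 101 ± 1.04 to 211 ± 11.2 TPM (adjusted p = 0.0051). Besides NEAT1, ZNF528-AS1 fell 5.35-fold to 8.94 ± 0.387 TPM in clone 1 and 0.296 ± 0.129 TPM in clone 2, the protein kinase inhibitor PKIB 4.85-fold from 28.8 ± 1.23 to 7.07 ± 6.05 TPM (adjusted p = 0.0019) and ZNF248 3.83-fold to 4.77 ± 5.50 TPM, though clone 1 was at 0.0164 TPM and clone 2 at 9.53 TPM for ZNF248. In the authors' tables SHISA2 passed for neither clone (adjusted p = 0.064 and 0.17), ZNF528-AS1 not for clone 1 (adjusted p = 0.071) and ZNF248 not for clone 2 (adjusted p = 0.68). CXCL11 was between 0 and 0.433 TPM in the 6 CTR libraries of cortical, hepatic and lung organoids, and between 8.57 and 48.1 TPM in the 4 CTR libraries of hESC and nephron organoids.

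No list had a member called in cortical organoids. All 10 interferon-response genes were higher when adjusted over the list alone and 0 over all genes; the first of them, ISG15, was at 471 ± 631 TPM in the clones and 27.7 ± 6.79 TPM in CTR (adjusted p = 0.19), and the set was called by camera (adjusted p = 3e-14) but not with an estimated correlation (adjusted p = 0.56). Of 16 cholesterol genes 8 were lower when adjusted over the list alone. Of 15 immediate early genes 6 were higher when adjusted over the list alone, FOS standing at 29.3 ± 31.7 against 2.55 ± 0.291 TPM (adjusted p = 0.19). MALAT1, the transcript next to NEAT1, was at 325 ± 115 against 355 ± 82.7 TPM (adjusted p = 0.83). Limma called 14 of 19393 genes, 10 up and 4 down, all by at least 2-fold. The count became 7 or 3 without one of the CTR libraries and 67 without the first library of clone 2.

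**Figure D3:**
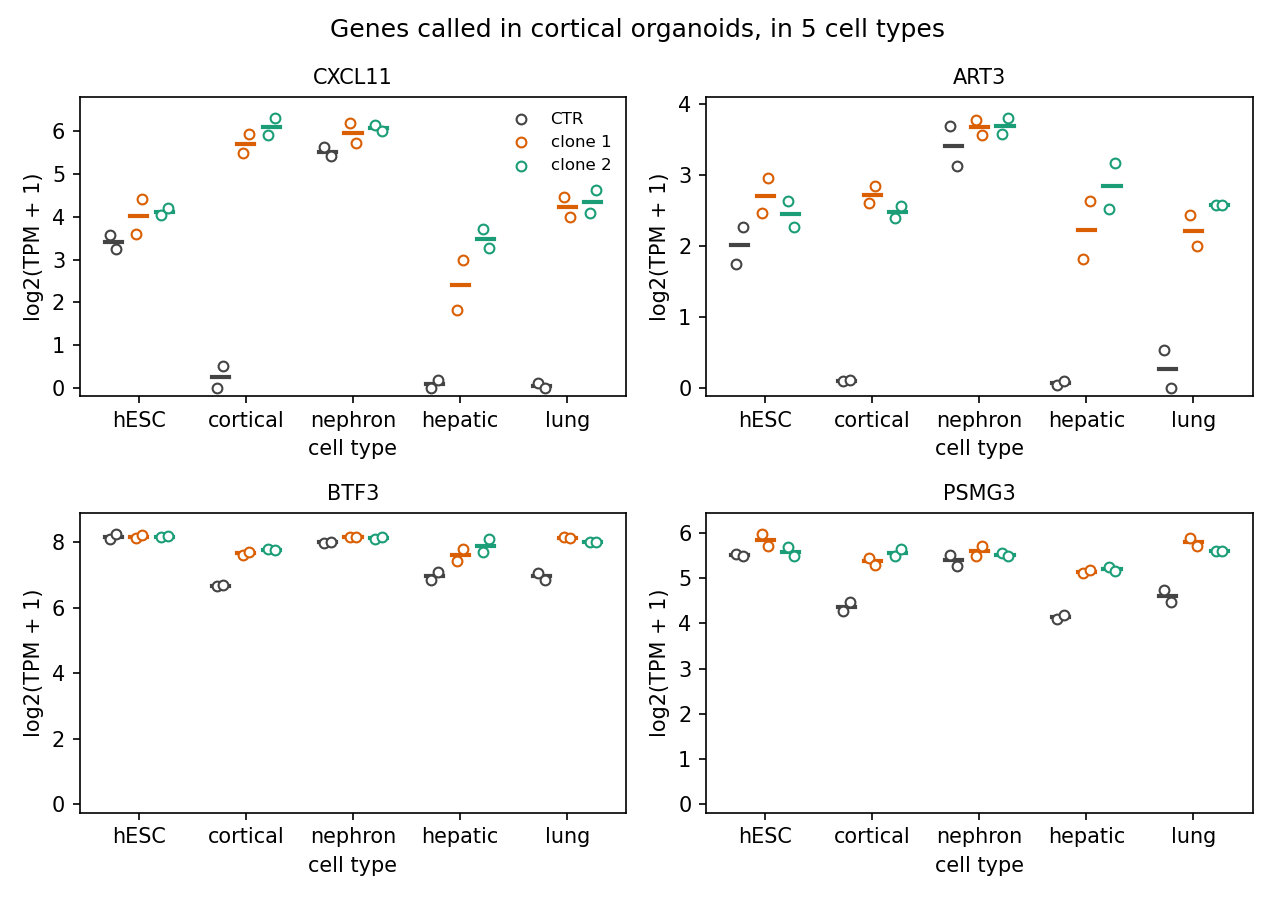
CXCL11, ART3, BTF3 and PSMG3 in CTR, clone 1 and clone 2 of 5 cell types on a log2(TPM + 1) scale; points are single libraries and bars are means of 2 libraries. CTR of cortical, hepatic and lung organoids lay below the clones for all 4 genes, with CXCL11 at 0 to 0.433 TPM there against 8.57 to 48.1 TPM in CTR of hESC and nephron organoids.

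In nephron organoids, where NEAT1 fell 29.9-fold, several falls passed in the averages of both clones. The water channel AQP1 fell 15.1-fold from 272 ± 223 to 19.9 ± 21.7 TPM (adjusted p = 0.022), sarcolipin (SLN) 12.8-fold from 16.5 ± 15.8 to 0.0561 ± 0.112 TPM (adjusted p = 0.017), the mesodermal factor TBX20 8.54-fold to 2.54 ± 1.80 TPM (adjusted p = 0.018), nephronectin (NPNT) 8.46-fold to 7.62 ± 4.12 TPM (adjusted p = 0.017) and fibromodulin (FMOD) 8.36-fold from 174 ± 67.2 to 23.1 ± 15.3 TPM (adjusted p = 0.0033). In the authors' tables AQP1, TBX20 and FMOD passed for clone 1 and not for clone 2 (adjusted p = 0.21, 0.32 and 0.2). Of 10 endothelial genes 7 fell, among them the VEGF receptor KDR 4.41-fold from 132 ± 4.11 to 31.3 ± 13.9 TPM (adjusted p = 0.0025), TEK 4.11-fold, EMCN 3.07-fold and VE-cadherin (CDH5) 2.60-fold, and the list fell by camera (adjusted p = 4e-07, and adjusted p = 0.31 with an estimated correlation). Of 13 stromal genes 5 fell, among them DCN 5.57-fold, LUM 3.88-fold, COL3A1 3.81-fold from 2775 ± 632 to 749.9 ± 252 TPM (adjusted p = 0.0038) and COL1A1 2.95-fold. Podocalyxin (PODXL) fell 6.17-fold to 17.5 ± 3.11 TPM and TCF21 2.78-fold, as 2 of 5 podocyte genes. Of 18 hepatoblast genes 5 fell, among them AFP 3.65-fold to 15.8 ± 1.27 TPM, AHSG 2.51-fold, CEBPA 2.06-fold and APOB 2.05-fold.

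Rises in the nephron clones were larger in clone 1 for SOX10 and FOXD3. The neural crest factor SOX10 rose 7.80-fold from 0.984 ± 0.322 to 17.0 ± 10.8 TPM (adjusted p = 0.0038) and FOXD3 5.27-fold to 6.72 ± 6.46 TPM (adjusted p = 0.0097), with the antisense RNA FOXD3-AS1, which overlaps it, 6.02-fold to 8.65 ± 8.86 TPM. Clone 1 and clone 2 stood at 25.8 ± 5.76 and 8.13 ± 2.61 TPM for SOX10 and at 11.6 ± 5.39 and 1.81 ± 0.0961 TPM for FOXD3. In the authors' tables SOX10, FOXD3, FOXD3-AS1, POU3F3 and WNT1 passed for clone 1 and not for clone 2 (adjusted p = 0.055, 0.089, 0.091, 0.26 and 0.13). Of 8 neural crest genes 4 rose, TFAP2B 3.37-fold among them. The homeobox factor EMX2 rose 5.23-fold from 3.33 ± 0.234 TPM (adjusted p = 0.0051) and the ligand WNT1 5.16-fold to 13.0 ± 9.52 TPM (adjusted p = 0.027). Of 8 tubule genes 4 rose, POU3F3 5.42-fold, CDH6 4.87-fold to 30.7 ± 16.2 TPM, MAL 2.24-fold and JAG1 1.98-fold, and of 11 nephron progenitor genes 2 rose, PAX2 3.27-fold to 45.7 ± 21.9 TPM (adjusted p = 0.0063) and SALL1 1.97-fold to 108 ± 31.9 TPM (adjusted p = 0.0048). POU3F3 also rose in CTR cortical organoids against hESC, so it is not particular to tubule. Of 16 cholesterol genes 10 rose and 14 rose when adjusted over the list alone, with HMGCS1 2.52-fold, INSIG1 2.34-fold and IDI1 2.10-fold higher. By camera the cholesterol list rose (adjusted p = 3e-11, and adjusted p = 0.31 with an estimated correlation).

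Among other lists in nephron organoids, the yolk-sac and endoderm factor GATA6 fell 4.02-fold and CXCR4 rose 1.78-fold, keratin KRT19 fell 2.79-fold from 869.5 ± 11.9 to 313 ± 41.4 TPM, TGFB2 fell 4.34-fold and NUAK2 rose 1.71-fold. Of 13 cell cycle genes 2 rose, CCNA2 and E2F1, each 1.43-fold, and of 9 imprinted genes 3 fell, DLK1 2.02-fold, PLAGL1 1.47-fold and MEST 1.39-fold. For YAP targets the median change was 0.16 and the mean -0.02, and for cholangiocyte genes the median was 0.49 and the mean -0.09, so median and mean differed in sign. Limma called 1494 of 20670 genes, 451 up and 1043 down, with 114 rises and 526 falls of at least 2-fold. The count became 732 or 598 without one of the CTR libraries, 723 or 550 without one of clone 1 and 540 or 235 without one of clone 2; clone 1 alone gave 1611 and clone 2 alone 175.

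In hepatic organoids NEAT1, 31.3-fold lower, was the only gene limma called in a fit of these 6 libraries, with 2307 at unadjusted p under 0.05. The pooled fit of the 30 CTR and knockout libraries called 1347, 691 up and 656 down, and the authors' tables list 581 and 554 genes for the 2 clones, 55 up and 86 down in both. Albumin (ALB) was at 409.5 ± 312 TPM in the clones and 51.0 ± 28.6 TPM in CTR (adjusted p = 0.47), AFP at 17270.3 ± 10569 and 6593 ± 1208 TPM (adjusted p = 0.57) and KRT19 at 1172 ± 373 and 2729 ± 342 TPM (adjusted p = 0.34), none of which passed. All 11 interferon-response genes were higher when adjusted over the list alone and 0 over all genes, ISG15 standing at 176 ± 117 against 46.2 ± 9.49 TPM (adjusted p = 0.33); camera called the set (adjusted p = 8e-09, and adjusted p = 0.51 with an estimated correlation). The count became 0 without either CTR library and 53 without the second library of clone 2.

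In lung organoids NEAT1, 16.3 ± 7.75 TPM in CTR, did not pass (adjusted p = 0.25), and limma called 0 genes, with 595 at unadjusted p under 0.05, against 21 in the pooled fit of 30 libraries and 13 and 19 in the authors' tables. Camera called the 16 cholesterol genes lower (adjusted p = 3.7e-10, and adjusted p = 0.96 with an estimated correlation). The matricellular protein CCN1 was at 130.5 ± 47.0 TPM in the clones and 172 ± 59.5 TPM in CTR (adjusted p = 0.99), MT-ND1 at 8454 ± 468 and 10118 ± 180.3 TPM, and FOS at 37.4 ± 16.4 and 41.6 ± 10.2 TPM. The 2 CTR libraries of lung organoids differed from each other, with r = 0.932 between them, and without the first of them the count became 356.

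The change was then averaged over the 5 cell types, which does not make it alike in each. NEAT1 fell 11.4-fold (adjusted p = 1e-14). The interferon-stimulated gene ISG15 rose 2.03-fold (log2 change 1.02 ± 0.20, adjusted p = 0.0091), the only one of 5 interferon-response genes called over all genes, while all 5 rose when adjusted over the list alone (camera adjusted p = 0.00024, and adjusted p = 0.27 with an estimated correlation). In hESC, cortical, nephron, hepatic and lung libraries ISG15 changed by 0.28, 3.19, -0.30, 1.63 and 0.30 (interaction adjusted p = 0.014). The tight junction protein CLDN3 rose 1.33-fold (adjusted p = 0.03) and POLA2, a subunit of DNA polymerase alpha near NEAT1, 1.21-fold (adjusted p = 0.012). The cardiac actin ACTC1 fell 1.55-fold (adjusted p = 0.0078) and podocalyxin (PODXL) by 0.58 on the log2 scale (adjusted p = 0.018). ACTC1 changed by -2.24 in hepatic organoids, where it was not called, and by -0.75 to 0.09 elsewhere (interaction adjusted p = 0.0075), and PODXL by -2.63 in nephron organoids, with -0.25 to 0.06 elsewhere (interaction adjusted p = 0.0017). Limma called 192 of 16217 genes measured in every cell type, 97 up and 95 down, 12 of them by at least 2-fold; the share that rose was 50.5%, or 33.9% after rescaling. The count became 103 or 121 without one of the CTR libraries of hESC, 119 without the first CTR library of hepatic organoids, 330 and 336 without the first library of hepatic clone 1 and the second of hepatic clone 2, and 1271 without the first CTR library of lung organoids.

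The interaction asked which genes responded differently between cell types, and limma called 360. In the order hESC, cortical, nephron, hepatic and lung, the log2 changes of CXCL11 were 0.64, 5.64, 0.50, 2.85 and 4.23 (adjusted p = 1.1e-06), and those of NEAT1 -1.46, -2.72, -4.90, -4.97 and -3.51 (adjusted p = 1.9e-05). With every clone near 0, the NEAT1 values on this scale followed the CTR level, and the authors' tables order the cell types differently. The adaptor protein gene DOK4 changed by -1.24 in nephron organoids, in the same direction in hepatic organoids, and by -0.01, 0.06 and 0.21 in hESC, cortical and lung organoids, and PKIB changed by -0.30, -2.28, 0.13, -0.68 and -2.05 (adjusted p = 0.00012 for each). For PKIB the values in hESC and nephron organoids average clones that moved in opposite directions: CTR, clone 1 and clone 2 were at 20.0, 54.0 and 4.28 TPM in hESC and at 10.2, 34.6 and 3.24 TPM in nephron organoids. The long non-coding RNA EGILA changed by -2.08, -0.01, -0.21, 0.33 and 0.53 (adjusted p = 0.00036) and BTF3 by -0.00, 1.05, 0.15, 0.79 and 1.12 (adjusted p = 0.00052). Without one of the CTR libraries the count of 360 became 2677 or 715 for lung, 225 or 172 for nephron, 232 for the first of hESC and 190 for the first of hepatic organoids. It became 216 without the second library of nephron clone 1, 210 without the second of nephron clone 2 and 1344 without the second of hepatic clone 2.

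The clones were also compared with each other. ZNF248 was at 7.53 ± 2.73 TPM in clone 2 and 0.00327 ± 0.0103 TPM in clone 1 over the 5 cell types (adjusted p = 1.9e-11). LRRC61, a leucine-rich repeat gene, was 6.42-fold higher in clone 2 at 29.9 ± 9.51 TPM (adjusted p = 4.1e-12) and CEBPZOS 2.36-fold (adjusted p = 6.5e-08). ZNF619 was 1.59-fold, the ubiquitin ligase ZNRF1 1.58-fold and the lysyl-tRNA synthetase KARS1 1.56-fold higher. PKIB was 5.90-fold lower in clone 2, at 3.74 ± 2.79 against 27.4 ± 16.5 TPM (adjusted p = 9.9e-13), the chemokine XCL1 2.85-fold, the ribosome export factor NMD3 2.02-fold, WDR72 1.93-fold and GAS8 1.76-fold lower. Limma called 87 genes, 55 higher and 32 lower in clone 2, and the count became 192 without the second library of hepatic clone 1 and 467 without the first of hepatic clone 2.

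Tested one clone at a time against the shared CTR libraries, 12 genes rose and 43 fell in both clones in hESC, where independent lists would share 0.0265 and 0.157 by chance. The same counts were 6 and 1 in cortical organoids against 0.00603 and 0.00186, 13 and 138 in nephron organoids against 0.631 and 7.54, and 0 and 1 in hepatic organoids against 0 and 4.74e-05. Simulated data with no effect and no shift of CTR shared 0 genes in each cell type, so they cannot test for such a shift. Both tests use the same 2 CTR libraries (a split leaves 1 per clone), so the excess may come from shared controls. Across genes, which are not independent replicates, the changes of the 2 clones correlated at 0.64 in hESC, 0.48 in cortical, 0.76 in nephron, 0.53 in hepatic and 0.35 in lung organoids, where simulated data without any effect gave 0.50 from the shared controls alone. The covariances were 0.0651 against a simulated 0.0280 in hESC, 0.0692 against 0.0513 in cortical, 0.187 against 0.0467 in nephron, 0.148 against 0.0827 in hepatic and 0.0505 against 0.0793 in lung organoids.

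In the authors' deposited tables, made from counts by DESeq2, NEAT1 changed by -7.70 and -4.69 on the log2 scale in clone 1 and clone 2 of hESC, by -5.90 and -4.68 in cortical, -10.61 and -6.00 in nephron, -7.42 and -6.42 in hepatic and -6.19 and -4.73 in lung organoids. At an adjusted p under 0.05 these tables list 417 and 998 genes for the 2 clones in hESC, 133 and 480 in cortical, 2460 and 712 in nephron, 581 and 554 in hepatic and 13 and 19 in lung organoids. All 115 hESC genes, 14 cortical genes and 1468 nephron genes that limma called and the tables hold had the same sign in the averages of both tables. Genes listed for both clones in one direction were 67 up and 181 down in hESC, 220 and 374 in nephron, 41 and 18 in cortical, 55 and 86 in hepatic and 4 and 1 in lung organoids. Both clones of a cell type are compared with the same CTR libraries, so these overlaps are not independent.

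How far each organoid type had moved from hESC was asked with the CTR libraries, 2 against 2. In cortical organoids at day 19 genes of the neural fate rose from little or nothing. The nuclear receptors NR2F1 and NR2F2, which pattern the cortex, were at 538 ± 76.6 and 426 ± 82.9 TPM and listed at 0 in hESC (adjusted p = 1e-06 and 1.4e-06), and BARHL1, a neuronal homeobox factor, was at 261 ± 91.8 TPM and listed at 0 in hESC. The secreted pentraxin PTX3 rose 293-fold to 619 ± 63.1 TPM (adjusted p = 1.9e-06), the ligand WNT7B 286-fold to 329 ± 57.3 TPM (adjusted p = 1.4e-06) and the antisense RNA LHX5-AS1 397-fold to 481 ± 75.3 TPM. Of 11 neural progenitor genes 10 rose, among them SOX1 109.7-fold to 140.0 ± 6.66 TPM, PAX6 107-fold to 128 ± 23.5 TPM and FABP7 103-fold to 532 ± 31.2 TPM. Of 12 neuron genes 9 rose, with STMN2 28.8-fold, DCX 18.5-fold, TBR1 14.9-fold and SLC17A6 12.2-fold higher. Of 7 tubule genes 6 rose, POU3F3 79.2-fold and LRP2 26.7-fold, and of 8 imprinted genes 7, DLK1 53.1-fold and NNAT 29.1-fold. EOMES, a factor of both primitive streak and cortical progenitors, rose 45.4-fold to 55.7 ± 12.3 TPM.

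All 12 pluripotency genes fell in cortical organoids. The stem-cell RNA ESRG fell 1856-fold from 1929 ± 6.03 to 0.0405 ± 0.0572 TPM (adjusted p = 4.6e-07), the Nodal co-receptor TDGF1 942-fold from 989 ± 36.2 TPM, L1TD1 309-fold from 677 ± 36.2 to 1.90 ± 2.68 TPM and VRTN 137-fold. LINC00678 and LINC00458, at 603 ± 7.39 and 283 ± 37.0 TPM in hESC, were listed at 0. Of 14 cell adhesion genes 13 fell, with CDH1 225-fold lower (266 ± 4.28 to 0.190 ± 0.0610 TPM), CLDN6 85.0-fold, EPCAM 74.2-fold and DSP 60.1-fold. The VEGF receptor KDR fell 95.7-fold and the transcription factor MYC 19.6-fold. Of 16 cholesterol genes 10 rose and 2 fell, HMGCS1 rising 9.17-fold to 458 ± 35.1 TPM. Camera called pluripotency (adjusted p = 1.1e-07, and adjusted p = 0.74 with an estimated correlation) and cell adhesion (adjusted p = 2.8e-05, and adjusted p = 0.74 with an estimated correlation) lower. Lists with a median and a mean of opposite sign were lung (0.48 and -0.37), gut and pancreas (-0.21 and 0.53), ER stress (0.18 and -0.06), interferon (-0.37 and 0.05) and mitochondrial (-0.07 and 0.16). Limma called 13559 of 19854 genes, 7107 up and 6452 down.

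In nephron organoids at day 13 type III collagen (COL3A1) rose 2682-fold from 0.0217 ± 0.0307 to 2775 ± 632 TPM (adjusted p = 1.8e-05), the mesodermal factor HAND1 579.9-fold to 676 ± 147 TPM and the growth factor IGF2 295-fold from 2.79 ± 0.461 to 1195 ± 620.3 TPM. HOXB9, a factor of posterior identity, was at 670.4 ± 40.9 TPM and lumican (LUM) at 300.0 ± 167 TPM, both listed at 0 in hESC, and the antisense RNA HOXB-AS3 rose 261-fold to 273 ± 24.4 TPM. Of 13 stromal genes 12 rose, TWIST1 106-fold to 173 ± 1.84 TPM and MEOX1 78.9-fold. Of 11 nephron progenitor genes 10 rose, PAX8 17.5-fold to 22.1 ± 18.3 TPM and WT1 13.8-fold to 13.9 ± 3.76 TPM, with HOXA11 at 21.7 ± 16.8 TPM and listed at 0 in hESC. All 6 tubule genes rose, GATA3 24.5-fold and CDH6 4.47-fold, and 3 of 5 podocyte genes, TCF21 6.75-fold among them. Of 18 hepatoblast genes 17 rose, APOA1 74.6-fold and AFP 44.7-fold to 61.3 ± 16.3 TPM, and of 10 endothelial genes 8, CDH5 25.0-fold and ESAM 13.5-fold.

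Of 16 hypoxia and glycolysis genes 14 rose in nephron organoids, NDRG1 36.3-fold to 132 ± 18.2 TPM, PFKFB3 17.6-fold and the glucose transporter SLC2A1 from 98.1 ± 16.5 to 885 ± 22.9 TPM (camera adjusted p = 0.00075, and adjusted p = 0.55 with an estimated correlation). All 12 pluripotency genes fell, L1TD1 442-fold, TDGF1 543-fold and POU5F1 134-fold from 139.8 ± 15.4 to 0.0486 ± 0.0687 TPM (adjusted p = 2.5e-05), and ESRG was listed at 0. LNCPRESS2 fell 181-fold and LINC00458 258-fold, while LINC00678 was listed at 0. Of 13 cell cycle genes 11 fell, MCM5 4.33-fold and AURKB 2.94-fold, and of 12 mitochondrial mRNAs 11 fell, MT-CO2 2.81-fold. Mitochondrial mRNAs held 9.33% of TPM in nephron organoids and 19.0% in hESC. Limma called 14067 of 20564 genes, 9729 up and 4338 down. The median change over all genes was 0.39 on the log2 scale, and 0.06 after rescaling by size factors, when the share that rose went from 69.2% to 51.9%; changes here are therefore read relative to 0.39. Camera sets a list against all other genes, so YAP targets with a median of 0.10 and a mean of 0.36 had the direction down; p53 targets had a median of -0.01 and a mean of 0.27.

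In hepatic organoids at day 21 all 20 hepatoblast genes rose. Alpha-fetoprotein (AFP) rose 4772-fold from 0.386 ± 0.296 to 6593 ± 1208 TPM (adjusted p = 2.5e-05), and the lipoproteins APOA2 732-fold to 916 ± 2.25 TPM and APOA1 676-fold to 1381 ± 18.1 TPM; transthyretin (TTR) was at 779 ± 10.7 TPM and listed at 0 in hESC. COL3A1 rose 1804-fold to 1909.7 ± 714 TPM, HAND1 1056-fold and IGF2 884-fold to 3364 ± 617 TPM. Of 8 endoderm genes 7 rose, GATA6 119.7-fold to 127 ± 5.49 TPM, CXCR4 35.9-fold and FOXA2 19.1-fold. Of 12 stromal genes 11 rose, PRRX1 32.3-fold, and of 15 matrix and integrin genes 11, the fibronectin gene FN1 44.3-fold and the vitronectin gene VTN 231-fold. KRT19 rose 14.0-fold to 2729 ± 342 TPM as 1 of 4 among 6 cholangiocyte genes. Of 16 hypoxia and glycolysis genes 15 rose, NDRG1 82.9-fold and SLC2A1 16.6-fold to 1631 ± 35.1 TPM. Of 8 interneuron genes 6 rose, GAD1 19.8-fold, and of 8 primitive streak genes 7, MIXL1 16.6-fold, CER1 15.2-fold to 62.6 ± 14.7 TPM and TBXT 6.87-fold.

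All 12 pluripotency genes fell in hepatic organoids, ESRG 6.23-fold to 309 ± 17.4 TPM, L1TD1 5.01-fold, DNMT3B 4.60-fold and PRDM14 4.21-fold to 22.9 ± 8.32 TPM. Among the largest falls were those of CUZD1, 47.4-fold from 91.2 ± 6.04 TPM, P3H2-AS1, 39.4-fold from 172 ± 1.29 TPM in CTR hESC, where the hESC of the PF-127 series had 1.60 to 4.26 TPM, the activin subunit INHBE, 30.8-fold to 5.69 ± 1.20 TPM, CH25H, 20.7-fold, and CHAC1, 19.3-fold to 9.86 ± 0.201 TPM. Of 13 cell cycle genes 11 fell, AURKB 4.30-fold and MKI67 3.39-fold, and of 12 mitochondrial mRNAs 8, MT-ND3 2.18-fold. Camera called hepatoblast genes higher (adjusted p = 4.5e-10, and adjusted p = 0.49 with an estimated correlation). The ER stress genes had a median of 0.54 and a mean of -0.07, and the lung genes a median of -0.50 and a mean of 0.04. Limma called 12397 of 20149 genes, 6950 up and 5447 down, and 8072 without the second CTR library of hESC.

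In lung organoids at day 19, of 9 lung genes measured 1 rose, the homeobox factor IRX1, 5.72-fold to 28.1 ± 20.4 TPM (adjusted p = 0.035), and NKX2-1, first of the list and a factor of lung and forebrain, was at 0.950 ± 1.05 TPM and listed at 0 in hESC. The largest rises were those of the imprinted gene DLK1, 141-fold to 272 ± 97.7 TPM (adjusted p = 0.0074), the YAP target ANKRD1, 114-fold to 124 ± 5.11 TPM (adjusted p = 0.0068), the antiproliferative gene BTG2, 111-fold to 177 ± 53.4 TPM, DIO3, which inactivates thyroid hormone, 64.8-fold to 69.2 ± 7.21 TPM, and IER5L, 50.5-fold; HOXB9 was at 84.2 ± 89.4 TPM and listed at 0 in hESC. Of 16 cholesterol genes 13 rose, INSIG1 22.4-fold to 405 ± 165 TPM, HMGCS1 9.93-fold, MSMO1 9.24-fold and IDI1 8.10-fold (camera adjusted p = 4.8e-07, and adjusted p = 0.77 with an estimated correlation). Of 12 YAP targets 7 rose, CCN1 3.15-fold to 172 ± 59.5 TPM, and of 14 immediate early genes 8, DUSP1 9.47-fold and JUNB 6.80-fold. Of 8 interferon-response genes 4 rose, ISG15 5.25-fold to 199.9 ± 44.2 TPM, and CDKN1A rose 15.6-fold.

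Of 12 pluripotency genes 5 fell in lung organoids, VRTN 7.00-fold, L1TD1 6.46-fold, ESRG 6.32-fold to 348 ± 239.5 TPM and DNMT3B 3.07-fold. P3H2-AS1 fell 99.8-fold, CUZD1 70.7-fold, CH25H to 0.376 ± 0.283 TPM, the VEGF receptor FLT1 19.2-fold to 1.39 ± 0.931 TPM, the kinase LCK 18.8-fold and NIBAN1 17.8-fold. For primitive streak genes the median was 0.20 and the mean -0.03, for neuron genes the camera direction was down and the fry direction up, and for choroid plexus genes the median was 0.06 and the mean -0.06. Limma called 6136 of 19305 genes, 3225 up and 2911 down. The count became 1239 or 1168 without one of the CTR libraries of hESC and 11179 or 11412 without one of lung organoids.

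**Figure D4:**
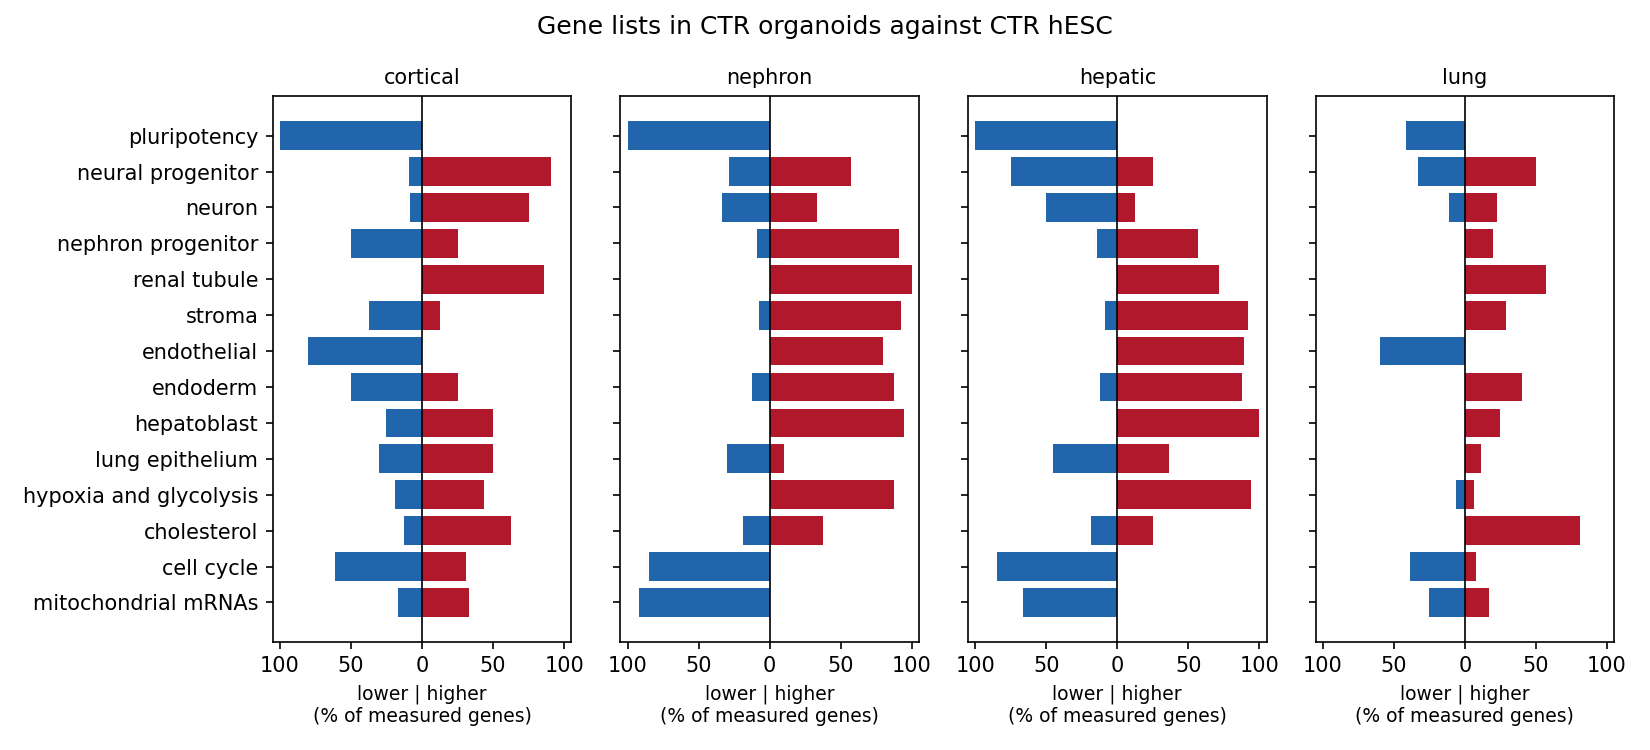
Percent of measured genes of 14 lists called higher or lower in CTR cortical, nephron, hepatic and lung organoids than in CTR hESC, 2 libraries per group. All 20 hepatoblast genes were higher in hepatic organoids, 10 of 11 neural progenitor genes in cortical organoids, 12 of 13 stromal genes in nephron organoids and 1 of 9 lung genes in lung organoids.

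Whether the conditions named PN96, Chip and SPIN in the labels differed was asked in WT organoids. In cortical organoids the PN96 libraries (day 53) were compared with the SPIN libraries (day 60), so that day and label cannot be told apart. IGFBP2, which binds insulin-like growth factors, was 99.6-fold higher in PN96, at 537 ± 61.2 against 4.39 ± 0.00814 TPM (adjusted p = 3.8e-05). The complex I subunit NDUFB7 was 89.9-fold higher, at 324 ± 23.0 against 3.51 ± 3.82 TPM, the neuronal protein CTXN1 73.6-fold, PPDPF 59.0-fold at 450.2 ± 8.41 against 6.66 ± 0.489 TPM (adjusted p = 2.2e-05), the chaperone HSPB1 50.5-fold at 429.7 ± 7.25 against 7.80 ± 3.09 TPM and CRIP2 45.2-fold. Transthyretin (TTR) was 173-fold lower, at 0.645 ± 0.102 against 794 ± 1049.8 TPM (adjusted p = 0.0078), COL3A1 98.9-fold at 6.72 ± 3.96 against 1217 ± 1398 TPM, LUM 57.0-fold, POSTN 47.8-fold, GPNMB 28.0-fold and IGFBP3 25.8-fold. Of 11 neural progenitor genes 6 were higher, LHX2 6.69-fold among them, and of 14 neuron genes 5, TUBB3 23.5-fold at 469 ± 50.9 TPM and BCL11B 8.42-fold. Of 9 interneuron genes 5 were higher, DLX1 32.3-fold at 187 ± 147 TPM among them.

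Of 13 cell cycle genes 11 were higher in PN96 than in SPIN, AURKB 7.03-fold, BIRC5 6.13-fold and MKI67 4.90-fold at 69.7 ± 4.83 TPM, and of 16 hypoxia and glycolysis genes 13, ADM 25.5-fold and SLC2A1 12.3-fold at 473 ± 7.28 TPM. Of 12 hepatoblast genes 8 were lower, AFP 13.0-fold and APOA2 15.3-fold and of 12 stromal genes 4, while of 11 ER stress genes 8 were lower and 2 higher, DDIT3 3.25-fold and XBP1 2.74-fold lower. By camera the hypoxia genes were higher (adjusted p = 5.5e-07, and adjusted p = 0.46 with an estimated correlation). Limma called 8468 of 21595 genes, 4757 higher and 3711 lower in PN96. Across genes, which are not independent replicates, Spearman's rho between the GC percent of a gene and its change was 0.50, and the median change was -0.38 among the genes of lowest GC and 1.16 among those of highest GC, each group holding 1 in 5 genes. After removing a smooth GC trend from each library, an alternative chosen after seeing the data, 2645 of the 4757 genes higher in PN96 were still called, and 2112 were not; the median change of all 4757 went from 1.46 to 0.84 and that of the 2112 from 1.27 to 0.20. IGFBP2 then stood at 6.08, NDUFB7 at 4.66, PPDPF at 3.54 instead of 5.88, CTXN1 at 3.14 instead of 6.20, HSPB1 at 3.93 instead of 5.66, CRIP2 at 3.47 instead of 5.50, TUBB3 at 3.36 instead of 4.55 and TTR at -7.25 on the log2 scale. Mitochondrial mRNAs held 13.4% of TPM in SPIN and 9.27% in PN96. The count became 4659 or 4699 without one of the PN96 libraries.

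Chip (day 54) was compared with SPIN (day 60) in the same fit. NDUFB7 was 77.8-fold higher at 281 ± 23.2 TPM, PPDPF 53.7-fold at 410.4 ± 40.7 TPM (adjusted p = 2.5e-05), CTXN1 45.5-fold and DLX1 45.8-fold at 222 ± 1.03 TPM (adjusted p = 0.0078), the hormone AMH 50.9-fold higher at 54.1 ± 6.65 TPM and the neuronal tubulin TUBB3 16.6-fold at 329 ± 20.0 TPM. TTR was 238-fold, LUM 71.5-fold, COL3A1 63.3-fold, GPNMB 57.2-fold, LINC02154 53.6-fold and POSTN 37.0-fold lower. Of 9 interneuron genes 5 were higher, DLX2 30.7-fold and DLX5 17.8-fold, of 13 cell cycle genes 11, AURKB 6.14-fold, and of 16 cholesterol genes 1 was higher and 9 lower, STARD4 by 2.33-fold. Limma called 7318 genes, 4600 higher and 2718 lower in Chip. With rho for GC at 0.49, 5004 were called after removing the GC trend, 3961 of them among the 7318. AMH then stood at 2.54 instead of 5.67, CTXN1 at 2.42 instead of 5.51, PPDPF at 3.38 instead of 5.75, NDUFB7 at 4.43 instead of 6.28 and TUBB3 at 2.85 instead of 4.05 on the log2 scale. The count became 3792 or 3339 without one of the Chip libraries.

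Between Chip and PN96 of cortical organoids, days 54 and 53, 19 genes differed. Of 16 hypoxia and glycolysis genes 4 were lower in Chip and all 16 when adjusted over the list alone. ADM, a vasodilator peptide, was 9.81-fold lower at 5.35 ± 0.807 against 61.8 ± 13.4 TPM (adjusted p = 0.035), SLC2A1 6.44-fold at 73.7 ± 17.8 against 473 ± 7.28 TPM (adjusted p = 0.03), NDRG1 4.51-fold (adjusted p = 0.041) and PFKFB4 3.62-fold (adjusted p = 0.041). The hexokinase HK2 was 4.77-fold lower at 77.6 ± 1.27 against 374 ± 17.3 TPM (adjusted p = 0.006), BHLHE40-AS1 4.97-fold and the histone gene H2BC8 4.54-fold. Higher in Chip were CHAC1 4.88-fold at 115 ± 10.6 TPM (adjusted p = 0.03), PSAT1, which makes serine, 2.71-fold at 398 ± 57.7 TPM, the tRNA synthetases TARS1 2.37-fold and IARS1 2.15-fold, and XBP1 2.11-fold (adjusted p = 0.043 for each of these 4). After removing the GC trend PSAT1, TARS1, IARS1 and XBP1 no longer passed (adjusted p = 0.057, 0.073, 0.079 and 0.061), though their changes stayed about as large, the log2 change going from 1.44 to 1.33, 1.25 to 1.15 and 1.10 to 1.01, and the fold of 2.11 for XBP1 to a log2 change of 0.97; after rescaling 1 gene was higher in Chip. Camera called the hypoxia list lower (adjusted p = 2.7e-28, and adjusted p = 0.18 with an estimated correlation). Of the 19 genes 6 were higher; the share that rose was 31.6%, or 7.14% after rescaling. The fit drew its spread from the SPIN libraries too: without one of them the count was 98 or 109, without either PN96 library 0, and without one of the Chip libraries 1 or 0.

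In hepatic organoids at day 17 Chip was compared with PN96. Higher in Chip were the Nodal inhibitors LEFTY1 11.8-fold at 89.4 ± 3.68 against 6.83 ± 2.18 TPM (adjusted p = 0.0071) and LEFTY2 7.79-fold at 118 ± 4.81 TPM (adjusted p = 0.0071). The muscle actin ACTA1 was 13.7-fold higher at 49.6 ± 0.188 TPM (adjusted p = 0.022), the hormone subunit CGA 11.2-fold at 46.9 ± 21.2 TPM, DDX43 8.45-fold and TTR 3.77-fold at 1006 ± 28.9 TPM (adjusted p = 0.045). AQP1 was 14.4-fold lower at 19.5 ± 7.78 against 295 ± 118 TPM (adjusted p = 0.023), the protease inhibitor SLPI 8.75-fold, MESP2 8.09-fold, LINC02772 7.91-fold and NDUFA4L2 7.89-fold (adjusted p = 0.0071), and LINC01866 11.5-fold to a listed value of 0. Of 16 hypoxia and glycolysis genes 11 were lower, NDRG1 3.69-fold and EGLN3 3.27-fold, and COL1A1 was 4.06-fold lower at 192 ± 1.48 TPM. Of 12 mitochondrial mRNAs 7 were higher, MT-ND2 2.39-fold at 10539 ± 319 TPM; they held 25.1% of TPM in Chip and 15.7% in PN96. Limma called 1577 of 20866 genes, 187 higher and 1390 lower, with a median change of -0.22 over all genes, or -0.01 after rescaling, so that changes are read relative to -0.22.

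After rescaling 533 genes were called between hepatic Chip and PN96, and the share that was higher in Chip went from 11.9% to 44.5%; without mitochondrial mRNAs, an alternative chosen after seeing the data, 494 were called, 475 of them among the 1577. Without one of the PN96 libraries of day 17 the count became 3 or 22, and without one of the Chip libraries 1 or 0. For cholangiocyte genes the median was 0.01 and the mean -0.15, and for endoderm genes -0.22 and 0.02. Between PN96 at day 21 and day 17, the chemokine CXCL11 was at 15.6 ± 0.661 TPM and listed at 0 at day 17 (adjusted p = 0.014), S100A9 was 16.5-fold higher at 37.0 ± 3.90 TPM (adjusted p = 0.014), HILPDA, a lipid droplet protein, 2.36-fold and the mitotic gene HMMR 2.21-fold. CHCHD2, a mitochondrial protein on chromosome 7 (GRCh38 56101569 to 56106576), was 44.9-fold lower at day 21, at 0.673 ± 0.349 against 73.4 ± 4.59 TPM (adjusted p = 0.014), AKR1B10 6.86-fold, FUT3 6.60-fold, TNFSF9 4.83-fold, RAB17 3.75-fold and MYCT1 3.68-fold. CHCHD2 was at 18.2 to 208 TPM in the other 14 WT organoid libraries and at 0 to 1.63 in CTR and knockout libraries. The WT libraries of day 21 may thus come from cells that differ. This was not tested, and such a difference cannot be told apart from day. Limma called 21 genes, 8 higher and 13 lower at day 21. That number fell with a pseudocount of 0.1, with the replicate block and without a filter. The count became 0 without either PN96 library of day 17, 2 without either Chip library and 11 without the second library of day 21.

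The CTR line and WT cells were compared where both had organoids of one kind. In hepatic organoids at day 21 CXCL11 was 15.6-fold lower in CTR, at 0.0674 ± 0.0953 against 15.6 ± 0.661 TPM (adjusted p = 0.029), MESP2 fell by 3.46 on the log2 scale to 2.15 ± 1.75 TPM, and WNT8A was lower 10.2-fold, CER1 7.82-fold at 62.6 ± 14.7 against 512 ± 215 TPM and EGFLAM-AS4 7.44-fold. The angiotensin receptor AGTR1 was 7.58-fold higher at 15.5 ± 0.847 TPM, GDF15 7.33-fold at 55.9 ± 1.10 TPM, GNRH2 7.24-fold, TG 6.89-fold and NDRG1 6.78-fold at 301 ± 32.1 TPM (adjusted p = 0.029 for AGTR1, GDF15, TG and NDRG1). Of 12 pluripotency genes 8 were lower in CTR, PRDM14 4.58-fold and ESRG 3.92-fold at 309 ± 17.4 TPM, of 13 cell cycle genes 11, MKI67 3.30-fold, and of 16 cholesterol genes 10, HMGCS1 2.73-fold. Of 15 immediate early genes 9 were higher, FOS 4.40-fold and DUSP1 4.41-fold. None of 20 hepatoblast genes passed over all genes, AFP standing at 6593 ± 1208 and 3089 ± 1609 TPM (adjusted p = 0.13). Limma called 1298 of 20214 genes, 499 higher and 799 lower, the share that rose going from 38.4% to 49.1% after rescaling. The count became 2001 or 350 without one of the WT libraries and 0 without either CTR library.

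In lung organoids CHCHD2 was the 1 gene called between CTR at day 19 and WT at day 20, at 0.158 ± 0.223 against 85.3 ± 1.88 TPM, 75.2-fold lower (log2 change -6.23 ± 0.29, adjusted p = 0.043), with 4227 genes at unadjusted p under 0.05. With a pseudocount of 0.1, without a filter, after rescaling and with the replicate block 0 genes were called. CHCHD2 ranged from 0 to 1.63 TPM over the 30 CTR and clone libraries, from 0 to 0.852 TPM over the PF-127 series and from 0.426 to 0.920 TPM in the WT hepatic libraries of day 21, and from 18.2 to 208 TPM in the other 14 WT organoid libraries. HMGCS1 was at 496 ± 43.2 and 199 ± 10.8 TPM (adjusted p = 0.098), and of 16 cholesterol genes 13 were higher in CTR when adjusted over the list alone. POU5F1 was not called (adjusted p = 0.36). The median change over all genes was -0.12, or -0.05 after rescaling, so that changes are read relative to -0.12. The count became 55 or 21 without one of the WT libraries and 3619 or 2363 without one of the CTR libraries.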

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

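The tests of whether the cortical knockout calls recur in other cell types, of scaling in hESC, of rises and falls apart in hESC and of genes of low GC were chosen after the result was seen, as was the removal of GC and length trends. The hESC test against the untreated libraries was written before its result, when levels of P3H2-AS1 and LINC01108 had been seen.

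The response to PF-127 differed between time points for 36 genes by the interaction test, led by HMOX1, SERPINB9, SFRP1 and ACSS2 (adjusted p = 0.0063 for each) and ITGB5 (adjusted p = 0.0093). The response to the knockout differed between cell types for 360 genes, led by CXCL11 (adjusted p = 1.1e-06), NEAT1 (adjusted p = 1.9e-05; its change on this scale follows its CTR level), PKIB (its clones moved in opposite directions in hESC and nephron organoids) and DOK4 (adjusted p = 0.00012 for each) and EGILA (adjusted p = 0.00036). In the WT nephron libraries of day 7, which entered no comparison, 8 of 12 nephron progenitor genes were at least 2-fold above both CTR libraries of hESC.

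The first pattern is that 4757 genes were lower in the cortical SPIN libraries than in PN96. GC bias of the SPIN libraries may account for part of it: rho between GC percent and change was 0.50 across genes, and 2645 stayed called once the GC trend was removed. The median change of the 4757 went from 1.46 to 0.84, with quartiles of 0.26 and 1.43 after. The other 2112 were lost because their median change went from 1.27 to 0.20 with a median standard error of 0.22 before and after. Against GC as the whole cause, 11.4% of the genes lower in SPIN with a known GC percent, 518 genes, had a GC percent of at most 45.9, where all 8169 genes had a median change of -0.35; this share lies just past the bound set for it. How much of the change of the other genes GC makes up stays open. Transcript length is argued against, since 4320 of the 4757 stayed called after its trend was removed. Day, the condition named SPIN and differences in cell make-up stay open and were not tested.

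The second pattern is the 14 genes called in cortical knockout organoids, CXCL11, ART3, BTF3 and PSMG3 among them. Signed by their cortical direction, the 13 without NEAT1 had a median change of 0.24 in hESC and 0.21 in nephron libraries, against 1.20 in hepatic and 1.72 in lung libraries, which argues against an absence of NEAT1 that acts alike in every cell type. Other nearby genes had a median signed change of 0.03 (0.38 near ZNF248). This argues against long gained or lost chromosome segments at most genes. Short ones stay open. CXCL11 was at 0 to 0.433 TPM in CTR cortical, hepatic and lung organoids and at 8.57 to 48.1 in CTR hESC and nephron organoids. These CTR cells may thus differ, which was not tested. WT hepatic libraries had NEAT1 at 16.4 and 18.4 TPM at day 21 and 21.5 to 30.7 TPM at day 17. Means of CXCL11, ART3, BTF3 and PSMG3 were 15.6, 5.51, 198 and 29.6 at day 21 and 0.0674, 0.0545, 125 and 16.6 in CTR. At day 17 PN96 and Chip had 0 and 0.0910, 0.277 and 0.757, 203 and 174, and 29.8 and 34.1 TPM. This argues against absence of NEAT1 as the cause for BTF3 and PSMG3 in hepatic organoids. For CXCL11 and ART3 it stays open, as does an effect limited to some cell types elsewhere.

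The third pattern is the 116 genes called in knockout hESC. Untreated hESC at 0 h of the PF-127 series, which express NEAT1, lay closer to CTR than to the clones for 84.6% of the 39 rises but 41.6% of the 77 falls, 56.0% of the 116 and 61.9% of all genes. Most falls thus lay closer to the clones, but with this few genes the shares of rises and falls do not settle it, so absence of NEAT1 and other differences of the CTR line cannot be told apart here. After rescaling 103 of the 116 stayed called, which argues against scaling as the cause of the count. P3H2-AS1 was at 172 TPM in CTR, 2.46 to 6.29 TPM in the clones of hESC and nephron organoids and 1.60 to 4.26 TPM in the PF-127 series. Differences between clones and CTR that arose in culture stay open.

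For PF-127 averaged over the time points, 1 of 100 relabellings, the real one, called as many as 40 genes. The median of the others was 0 and the highest 38, close to the real number, so chance is not excluded at that number. For the knockout averaged over cell types 1 of 100 relabellings, the real one, called as many as 192 genes, with 90 for the highest other. For clone 2 against clone 1 it was 2 of 100, with 87 genes; the highest other called 208, and what sets its samples apart was not tested.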

How the results depend on the processing

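The removal of GC and length trends, the fit without the SPIN libraries and the TPM without mitochondrial mRNAs were chosen after seeing the data. Counts are genes called, and the cause of a change was not tested unless stated.

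With a pseudocount of 0.1 the counts were 1 for PF-127 at 0 h and 1 at 1 h, 0 for the hepatic and 1 for the lung knockout, 6 for cortical Chip against PN96, 6 for hepatic day 21 against 17, 814 for hepatic CTR against WT and 0 for lung CTR against WT. Without a filter they were 1 at 0 h, 7 at 1 h, 63 for the PF-127 interaction, 4 for the cortical, 735 for the nephron and 0 for the hepatic knockout, 425 for the knockout average, 1064 for its interaction and 157 for the clones. They were then 1 for cortical Chip against PN96, 332 for hepatic Chip against PN96, and 0 each for hepatic day 21 against 17, hepatic CTR against WT and lung CTR against WT. The filter of 5 TPM gave 63 at 4 h, 57 for the PF-127 interaction and 290 for the hESC knockout; fewer genes were tested.

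Rescaling gave 63 for the PF-127 average, 533 for hepatic Chip against PN96 and 0 for lung CTR against WT. The replicate block gave 25 at 4 h, 68 for the hESC and 23 for the cortical knockout, 1 for cortical Chip against PN96, 3 for hepatic day 21 against 17 and 0 for lung CTR against WT. Replicate numbers do not pair the samples: residuals of like numbers correlated between -0.12 and 0.37 over pairs of knockout groups. A fit of 1 time alone called 0 at 4 h and 0 at 24 h, with fewer libraries to estimate the spread. The pooled fits gave 72, 88, 1347 and 21 for the knockout in hESC, cortical, hepatic and lung libraries and 9281 for lung organoids against hESC. Pooled fits can take too small a spread for genes expressed in 1 cell type. Clone 1 alone gave 71 in hESC, and clone 2 alone 25 in cortical and 175 in nephron organoids. Without the SPIN libraries cortical Chip against PN96 had 82, the 19 among them, and without mitochondrial mRNAs hepatic Chip against PN96 had 494, of which 475 were among the 1577. With an estimated correlation 4 list calls of camera held.

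Leaving out 1 library leaves a group of 1, assumed to vary like the other groups. The counts ranged from 0 to 0 at 0 h, 0 to 1 at 1 h, 2 to 192 at 4 h, 44 to 283 at 24 h, 5 to 64 for the PF-127 average and 1 to 65 for its interaction. For the knockout they ranged from 10 to 68 in hESC, 3 to 67 in cortical, 235 to 732 in nephron, 0 to 53 in hepatic and 0 to 356 in lung libraries, 103 to 1271 for the average, 172 to 2677 for the interaction and 63 to 467 for the clones. Against hESC they ranged from 9745 to 12531 for cortical, 9800 to 12107 for nephron, 8072 to 10833 for hepatic and 1168 to 11412 for lung organoids. In cortical WT organoids they ranged from 4659 to 8825 for PN96 against SPIN, 3339 to 7923 for Chip against SPIN and 0 to 109 for Chip against PN96. In hepatic organoids they ranged from 0 to 2326 for Chip against PN96, 0 to 14 for day 21 against 17 and 0 to 2001 for CTR against WT, and in lung organoids from 21 to 3619.

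Once the GC trend was removed, the log2 changes of ARHGEF17 (-0.25), BBC3 (-0.73) and ZNRD2 (-0.29) in PN96 against SPIN were reversed. In Chip against SPIN those of SOX1 (-0.01), EGFL7 (-0.13), BBC3 (-0.12), SDF2L1 (-0.28), TRIB3 (-0.07), RBM14 (-0.23), ZNRD2 (-0.14) and LTBP3 (-0.48) were; none was then called. Of 226 gene values 155 stayed on their side of the threshold, 60 kept their direction and passed no longer, and these 11 reversed.

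Of the gene values followed elsewhere, those that kept their call numbered 992 of 1052 with the pseudocount, 819 of 1052 without a filter, 939 of 941 with the stricter filter, 998 of 1050 after rescaling and 985 of 1052 with the block. They numbered 87 of 102 with clone 1 only and 39 of 102 with clone 2 only, 0 of 45 with 1 time alone, 70 of 102 in the pooled knockout fit, 513 of 530 in the pooled CTR fit and 4358 of 5684 with a library left out. After the data were seen, 217 of 226 kept it without the length trend, 12 of 12 without SPIN and 222 of 247 without mitochondrial mRNAs.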

Other observations

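The WT nephron libraries of day 7 were set beside CTR hESC as levels, without a test, and genes are the first or largest examples of lists chosen after their values were seen. Of 12 nephron progenitor genes 8 were at least 2-fold above both hESC libraries, CITED1 at 153 ± 29.2 against 2.37 ± 0.287 TPM and HOXD11 at 43.6 ± 23.0 and HOXA11 at 21.9 ± 6.19 TPM, both listed at 0 in hESC. SIX2 stood at 1.04 and 1.24 TPM and WT1 at 0.0680 and 0.0618 TPM. Of 10 primitive streak genes 6 were higher, TBXT at 76.4 ± 1.49 against 0.0925 ± 0.0284 TPM, of 13 stromal genes 9, COL1A2 at 327 ± 9.85 against 34.8 ± 1.77 TPM, and of 9 gut and pancreas genes 4, CDX1 at 235 ± 54.2 against 0.147 ± 0.0918 TPM. Of 13 pluripotency genes 11 were lower, POU5F1 at 0.128 ± 0.182 against 139.8 ± 15.4 TPM, and of 16 cell adhesion genes 10, CDH1 at 1.67 ± 0.0481 against 266 ± 4.28 TPM.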
